A study of Mus musculus with 6 samples.

How the data were processed

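Transcript levels were measured in J774A.1 cells, a mouse macrophage-like line of BALB/c origin, on 6 Affymetrix whole-transcript arrays. Per the labels' protocols, cells were grown in RPMI-1640 medium with 10% fetal calf serum to 80% confluence and received neuropeptide FF (NPFF) at 1 nM or the phosphate-buffered saline (PBS) vehicle for 18 h. Total RNA was extracted with TRIZOL, 500 ng per sample was used, and the targets were biotin-labelled with the manufacturer's terminal labelling kit. Groups were taken from the sample titles, which name 3 biological replicates of each group. The titles call the control cells non-treated and the treatment labels call them vehicle-treated; they are called control here. The labels do not say whether replicates were cultured on separate days, so p-values measure the spread between these samples.

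The deposited values are log2 intensities per transcript cluster, as read from their range of 4.59 to 14.0. The scanner software, background correction and normalization used by the authors are not given in the sources used here, nor is a genome build, and no coordinates are printed. The table held 33794 features. A platform annotation table paired 23521 of them with exactly 1 gene symbol and 1814 with several symbols, and left 8459 unnamed here. Features with several symbols or none entered the normalization, a count over all features and a comparison of unnamed with named features in control 1. The deposited arrays did not share 1 distribution, since the sorted values of an array departed from the mean of the arrays by up to 0.17 log2. Quantile normalization over all features was therefore applied, by a condition fixed before the data were examined. Where several features named 1 gene, the feature with the highest mean over the 6 arrays was kept; this applied to 1082 genes and gave 22180 genes. No dim features were removed. Arrays carry no counting depth, and their number, 3 per group, limits the precision.

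NPFF was compared with control by limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on group alone, 4 residual degrees of freedom and an estimated 2.49 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors (SE) are those of the moderated fit, and standard deviations (SD) are over the 3 arrays of a group.

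Before the data were examined, 34 gene lists were fixed. They covered alternative activation (M2) markers, classical activation (M1) markers, NF-kB pathway members, the type I interferon response, cell cycle and DNA replication, macrophage self-renewal genes, NPFF and RF-amide peptides and receptors, opioid and other neuropeptide genes, immediate-early and cAMP response genes, and STAT3/STAT6 signalling. Metabolic and stress lists covered cholesterol biosynthesis, LXR targets, fatty acid oxidation and PPAR targets, oxidative phosphorylation, glycolysis and hypoxia, the unfolded protein response, the NRF2 response, heat shock proteins, and p53 targets and apoptosis. Further lists held lysosome and autophagy, phagocytosis and scavenger receptors, antigen presentation, chemokines, macrophage identity, osteoclast differentiation, ribosomal proteins, replication-dependent histones and mitochondrially encoded genes. Markers of fibroblasts, epithelial and endothelial cells, lymphocytes, neutrophils and mast cells, dendritic cells and adipocytes completed the set. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move on balance in a common direction, were run beside it. With an estimated correlation, camera rests on the 4 residual degrees of freedom. It therefore had little power here, and a list that failed it may have failed for that reason alone. A list's median difference was also ranked among 10000 random lists of the same size matched on mean expression over 10 bins. Several lists share members, such as Cd36, Csf1r, Myc and Fcer1g, so their tests are not independent.

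Genes named in the text followed a rule fixed in advance. Genes past the threshold were to be named first; where fewer than 10 passed in a direction, genes whose groups did not overlap were added in order of p up to 10, leaving out predicted and other unnamed classes of symbols. In addition, 21 genes tied to NPFF signalling, macrophage activation and proliferation were fixed, together with up to 4 members of each list by p. Fixed genes and list members without a feature of their own were not analysed here.

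The scripts were tested on simulated data for the same comparison of 22180 genes, with 67, 67 and 66 genes changed by 0.5, 1 and 2 log2. With arrays of equal spread, 77.6%, 98.5% and 100% of them were recovered, with 13 false calls of 197. With the spread of the 6 real arrays, these shares were 34.3%, 77.6% and 93.9%, with 0 false calls of 137. Each scenario was simulated once. In a simulation for the gene lists, a shift of 0.15 log2 in the cell cycle list was called and none of the 33 other lists was. Its noise was independent between genes and equal across arrays, so it does not show how camera behaves with correlated genes or unequal arrays. In a further simulation without a treatment effect, control 1 carried its real deviation and the noise was otherwise the same. There 0 of 34 lists passed camera, at the preset or an estimated correlation. Both were run once.

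Alternatives fixed in advance were the replicate number as a block, leaving out each array in turn, centring on the array median, cyclic loess normalization, removal of the dimmest genes, a trended and robust prior, array weights, the mean over a gene's features, all features, an adjusted p under 0.10, a minimum change of 1.5-fold, a plain two-sample test without moderation, and the other list tests. Values as deposited, the removal of both control arrays that stood apart, and array weights by the gene-by-gene method were added after the data were seen. No batch, slide or scan date was given in the sources used here.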

Results

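The data collected were log2 transcript levels from 6 arrays of J774A.1 mouse macrophages, 3 from cells given NPFF at 1 nM for 18 h and 3 from cells given vehicle. NPFF is an amidated neuropeptide of the RF-amide family that signals through the G-protein-coupled receptors Npffr1 and Npffr2. The comparison addressed which transcripts differed after exposure to the peptide, with attention to macrophage activation state, proliferation and the NPFF receptors. Values are quantile-normalized log2 intensities of 22180 genes, and differences are NPFF minus control.

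The arrays of the NPFF group were more alike than those of the control group. Pearson's r across genes, which are not independent replicates, lay between 0.996 and 0.997 for pairs of NPFF arrays and between 0.965 and 0.996 for pairs of control arrays. The median SD of a gene was 0.07 in the NPFF group and 0.14 in the control group. Control 1 stood farthest apart, with an SD over genes of 0.36 from the mean of control 3 and the NPFF arrays, and control 2 followed at 0.17. Measured from the mean of the other 3 of these 4 arrays, control 3 stood at 0.11, within the NPFF arrays' range of 0.10 to 0.12. As deposited, control 1 also had the highest median, 6.38 against 6.24 to 6.29, and the narrowest interquartile range, 2.04 against 2.31 to 2.41. Mitochondrially encoded transcripts deviated from the mean of all arrays by 0.19 in control 1 and -0.14 in control 2, whereas the 3 NPFF arrays lay between -0.03 and 0.00. Each array differed from every other, so all 6 were kept as separate samples.

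**Figure D1:**
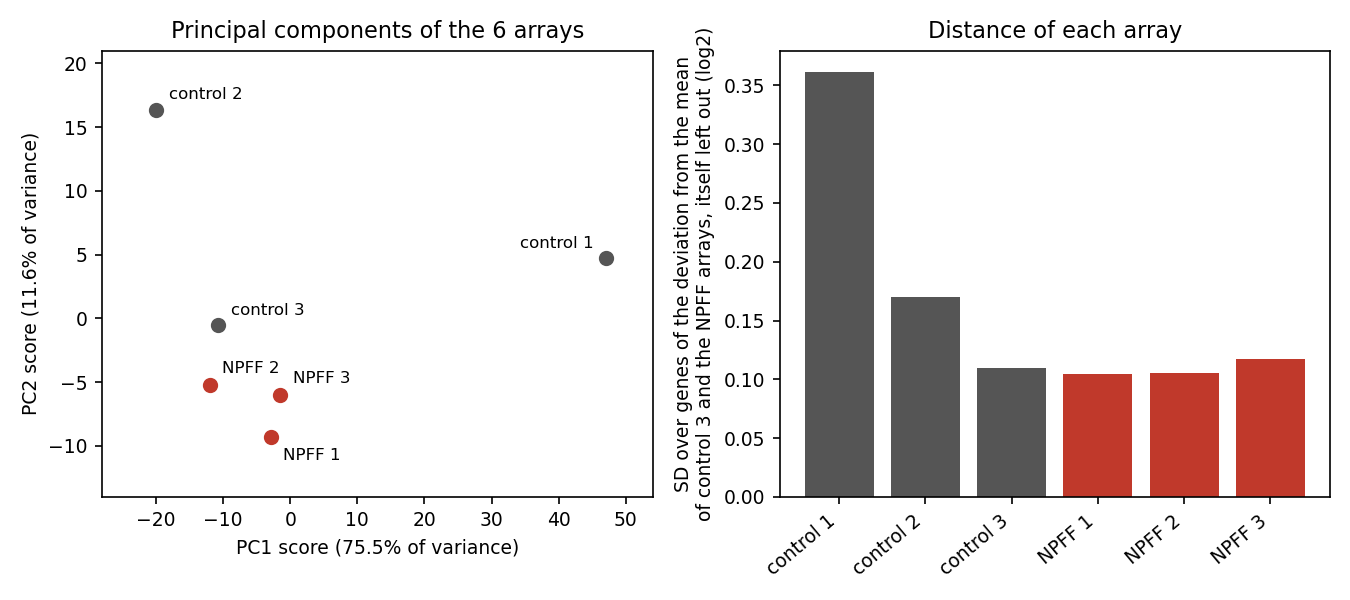
The left panel plots each array by its scores on the first and second principal components over all genes, which hold 75.5% and 11.6% of the variance, and the right panel gives for each array the SD over genes (log2) of its deviation from the mean of control 3 and the NPFF arrays, each of which is left out of its own reference. Grey marks control and red marks NPFF. Control 1 lies alone at 47.1 on the first component, and its SD of 0.36 and that of control 2, 0.17, exceed those of the other 4 arrays.

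Named here are the 10 genes of smallest p in each direction among those whose groups did not overlap, predicted and other unnamed classes of symbols left out. On the higher side, Slc6a12, a betaine and GABA transporter (feature 17462472), stood at 10.47 ± 0.10 (SD, n = 3) in control and 11.33 ± 0.14 (SD, n = 3) in NPFF, a difference of 0.86 (SE 0.10), or 1.82-fold. Snx9, a sorting nexin of endocytosis, differed by 0.52 (SE 0.06), Htr1b, a serotonin receptor, by 0.92 (SE 0.12), and Car2, a carbonic anhydrase, by 0.59 (SE 0.08). Tmem38b, a cation channel of the endoplasmic reticulum, had a difference of 0.97 (SE 0.17) and Slco4a1, an organic anion transporter, one of 0.86 (SE 0.17). Differences of 0.34 to 0.53 were measured for Agmo, an ether lipid monooxygenase, Itga4, the integrin alpha 4 chain, Atrn and the sodium pump subunit Fxyd2. On the lower side, Ifi204, an interferon-inducible DNA sensor (feature 17230045), stood at 7.42 ± 0.11 (SD, n = 3) in control and 6.82 ± 0.17 (SD, n = 3) in NPFF, and the scavenger receptor Cd36 (feature 17445715) at 11.39 ± 0.11 and 10.98 ± 0.05 (SD, n = 3 each). The pseudogene Rbx1-ps had a difference of -0.49 (SE 0.06), Fam171b -0.48 (SE 0.07) and the myeloid receptor Tarm1 -0.41 (SE 0.08). Trim30a, Mexis, Sqor, Dpep2 and the cytidine deaminase Apobec1 had differences between -0.36 and -0.28. In each of these 20 genes all NPFF arrays lay on the same side of all control arrays, and in none did leaving out 1 array move the difference by more than 1.5 times, as can be expected of genes chosen for a small p. Over all 88 genes whose differences were followed, it did so or turned the sign in 37.

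None of these genes passed the adjusted threshold, and the values are given as measured. By limma, 0 of 22180 genes had an adjusted p under 0.05 or under 0.10, and the smallest adjusted p was 0.789. At an unadjusted p under 0.05 there were 556 genes, 185 higher and 371 lower in NPFF. Evenly spread p-values would give 1109, but other splits of the 6 arrays into 3 and 3 gave between 174 and 2179. A count under 1109 is therefore not by itself unusual for these arrays. A plain two-sample test without moderation gave 724 such genes and 0 after adjustment. By limma over all 33794 features, 952 had an unadjusted p under 0.05 and 0 passed after adjustment. Values of the 2 groups did not overlap in 1904 genes, or 8.58%, where chance gives 10%; 813 of them were higher and 1091 lower in NPFF. Of the genes at an unadjusted p under 0.05, the share higher in NPFF was 33.3%, against 19.0% with the values as deposited and 12.1% with arrays centred on their medians, 42.4% after cyclic loess and 57.6% without control 2, where 379 were higher and 279 lower. Without control 1, 2 or 3, 2397, 658 and 937 genes reached that unadjusted level; without NPFF 1, 2 or 3 the counts were 235, 268 and 304, and without controls 1 and 2 together 1130. The adjusted count was 0 in each of these, but it was 1127 with array weights, whose estimation stopped before reaching its tolerance and gave control 3 a weight of 22.6 and control 1 a weight of 0.0773. With weights from limma's gene-by-gene method, where control 3 had a weight of 2.37, it was 0.

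Npffr1 (feature 17233716), a receptor of the added peptide, stood at 6.45 ± 0.03 (SD, n = 3) in control and 6.69 ± 0.06 (SD, n = 3) in NPFF, a difference of 0.24 (SE 0.06) with no overlap between groups. Npffr2, the other receptor, differed by 0.01 (SE 0.11), and Npff itself by -0.10 (SE 0.12). Of the 10 genes of NPFF and RF-amide peptides and receptors, 8 were higher in NPFF, including Prlh at 0.17, Kiss1 at 0.13 and Qrfp at 0.17, and the list passed camera with a mean difference of 0.07 (adjusted p = 0.0482). With an estimated correlation the adjusted p = 0.438, although the estimate of -0.050 was below the preset 0.01. No member passed limma over all genes or adjusted over the list alone. The call was lost without control 2 (adjusted p = 0.486), without control 3 (0.234) and without NPFF 1, 2 or 3 (0.0627, 0.0997 and 0.0699), with the dimmest genes removed (0.114), with the replicate number as a block (0.122) and with the mean over a gene's features (0.0514). Kiss1 differed by 0.07 without control 1, Qrfp by 0.07 without control 2 and Prlh by 0.10 without control 3. By mean signal, Kiss1 lay at the 9.6th percentile of all genes, Npffr2 at the 30.3rd and Npffr1 at the 50.9th, and the list's median was 44.5.

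Ndrg2, a member of the N-myc downstream-regulated family linked to growth control, stood at 9.10 ± 0.32 (SD, n = 3) in control and 9.67 ± 0.11 (SD, n = 3) in NPFF (feature 17306147). Its values were 8.74, 9.22 and 9.35 in the controls and 9.70, 9.55 and 9.76 in the NPFF arrays, a difference of 0.57 (SE 0.16). Against control 3 alone the difference was 0.32. Its relative Ndrg1 had a difference of -0.29 (SE 0.10), and Csf1r, the receptor for the macrophage growth factor CSF1, one of 0.46 (SE 0.20), with 10.81 ± 0.41 in control and 11.27 ± 0.05 in NPFF (SD, n = 3 each). Against control 3 alone, Csf1r differed by 0.15. Myc had a difference of -0.17 (SE 0.08). None of the 27 measured macrophage self-renewal genes passed limma over all genes or adjusted over the list alone. As a list, with 12 genes higher and 15 lower, they did not pass camera (adjusted p = 0.982), and the mean of 0.04 lay on the other side of 0 from the median of -0.01 and the test's direction.

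Cell cycle and DNA replication genes were higher in NPFF in 44 of 55 cases, with a mean difference of 0.14 and a median of 0.12. As a list they rose by camera (adjusted p = 5.2e-09), but with an estimated correlation the adjusted p = 0.438, and by fry the adjusted p = 0.521. The mean over the list was 9.68 ± 0.11 (SD, n = 3) in control and 9.82 ± 0.02 (SD, n = 3) in NPFF, and each NPFF array lay above each control, with control 1 the lowest at -0.19 from the mean of all arrays. The transcription factor Mybl2 had a difference of 0.38 (SE 0.12), Cdc20, an activator of the anaphase-promoting complex, 0.29 (SE 0.11), the helicase subunit Mcm7 0.27 (SE 0.12) and the mitotic kinase Aurka 0.17 (SE 0.07). The proliferation marker Mki67 stood at 11.54 ± 0.03 (SD, n = 3) in control and 11.64 ± 0.04 (SD, n = 3) in NPFF. No member passed limma over all genes or adjusted over the list alone; 20 were higher and 1 lower with no overlap between groups, where chance gives 10% of genes in both directions together. Without control 1 the mean difference was 0.07, with Mybl2 at 0.25 and Mcm7 at 0.15, and without controls 1 and 2 it was 0.07 (adjusted p = 6.9e-06 by camera). The 13 replication-dependent histones, which are made in S phase, did not pass (adjusted p = 0.278), with 9 higher, among them H1f5 at 0.25 (SE 0.08); their median of 0.09 turned to -0.04 without control 1, and 6 of 13 were higher against control 3 alone.

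Markers of both macrophage activation states were lower in NPFF, by small amounts. Of 30 alternative activation (M2) markers, 20 were lower, the mean difference was -0.07, and the list fell by camera (adjusted p = 0.0057; adjusted p = 0.438 with an estimated correlation). The list's mean in control 1, 7.08, lay within the NPFF range of 7.05 to 7.08, so the groups overlapped and the fall was against controls 2 and 3. The growth factor Igf1 had a difference of -0.42 (SE 0.11), the inhibitory receptor Cd200r1 -0.31 (SE 0.10), the lectin Mgl2 -0.29 (SE 0.13) and Socs2 -0.14 (SE 0.07). Differences of the commonly used M2 markers were close to their SE or below it. Arg1 had a difference of -0.07 (SE 0.07), Retnla -0.08 (SE 0.07), Mrc1 -0.12 (SE 0.09), Il4ra 0.12 (SE 0.20) and Chil3 0.01 (SE 0.42). By mean signal, Retnla lay at the 3.6th percentile of all genes and Chil3 and Arg1 at the 30.7th and 32.0th, so their small differences say little. Mrc1 and Il4ra lay at the 67.7th and 67.3rd. Without control 1, Mrc1 and Retnla differed by -0.03 each, and without control 3, Arg1 by -0.03 and Mgl2 by -0.18. Of 33 classical activation (M1) markers, 23 were lower, the mean difference was -0.07, and the list fell by camera (adjusted p = 0.0467; adjusted p = 0.438 with an estimated correlation). Il1a had a difference of -0.20 (SE 0.07), the costimulatory genes Cd40 and Cd80 -0.22 (SE 0.10) and -0.28 (SE 0.12), and the chemokine Ccl5 0.20 (SE 0.08). Without control 1, Cd80 differed by -0.14. With single arrays left out, Cd40 ranged from -0.28 to -0.14.

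The inflammatory genes fixed in advance had differences of -0.33 (SE 0.17) for Il6, -0.28 (SE 0.13) for Ccl2, 0.13 (SE 0.16) for Tnf, -0.03 (SE 0.09) for Nos2, -0.02 (SE 0.10) for Il1b, -0.02 (SE 0.06) for Il12b and -0.06 (SE 0.06) for Il10. Of these, Il10, Il12b and Il1b were dim, at the 12.2nd, 24.2nd and 28.1st percentiles of mean signal. Il6 and Nos2 lay at the 40.1st and 55.6th, and Ccl2 and Tnf at the 96.4th and 97.7th. The macrophage marker Adgre1, which encodes F4/80, differed by -0.19 (SE 0.11). Without control 1 these differences were -0.51 for Il6, -0.15 for Ccl2 and -0.30 for Adgre1. With single arrays left out, they ranged from -0.51 to -0.22 for Il6, -0.39 to -0.15 for Ccl2 and -0.30 to -0.09 for Adgre1. Il10 ranged from -0.08 to -0.03. No member of either activation list passed limma over all genes or adjusted over the list alone. Without control 3 the adjusted p was 0.0659 for the M2 list and 0.333 for the M1 list, and the M1 call was also lost without control 1 (0.0565), NPFF 1 (0.0693) or NPFF 3 (0.0835), and with the mean over a gene's features (0.0514). Npff, Il4ra and Tnf changed sign against control 3 alone, at 0.07, -0.17 and -0.08, as did Npffr2 at -0.14.

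Glycolysis and hypoxia response genes were higher in 21 of 30 cases, with a mean difference of 0.10, and the list rose by camera (adjusted p = 0.0215; adjusted p = 0.996 with an estimated correlation). Pkm, which makes pyruvate in glycolysis, had a difference of 0.34 (SE 0.14), the phosphofructokinase Pfkl 0.41 (SE 0.20), Tpi1 0.16 (SE 0.08) and the lactate exporter Slc16a3 0.48 (SE 0.27). Ribosomal protein genes were higher in 34 of 42 cases, with a mean of 0.09, and rose by camera (adjusted p = 0.0215; adjusted p = 0.996 with an estimated correlation). Rps23 had a difference of 0.21 (SE 0.08), Rpl14 0.22 (SE 0.12), Rps13 -0.20 (SE 0.09) and Rpl10a -0.19 (SE 0.09). Rpl10a ranged from -0.26 to -0.12 with single arrays left out. Both lists were lowest in control 1, at -0.23 and -0.26 from the mean of all arrays, and their group means overlapped. Without control 1 the glycolysis mean was 0.01 (adjusted p = 0.112) and the ribosomal mean -0.01 (adjusted p = 0.489), and Pkm differed by 0.17, Pfkl by 0.17, Tpi1 by 0.09, Slc16a3 by 0.15 and Rpl14 by 0.12. Without controls 1 and 2, which leaves control 3 alone, the ribosomal mean was -0.03 and 14 of 42 genes were higher. The glycolysis median was 0.05 there, and 24 of 30 genes were higher. The glycolysis call was lost as well without control 3 (0.0659), NPFF 1 (0.130) or the dimmest genes (0.0580), and the ribosomal call without control 2 (0.140), NPFF 2 (0.0731) or the dimmest genes (0.0743) and with the mean over a gene's features (0.0831). No member of these lists passed limma over all genes or adjusted over the list alone.

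**Figure D2:**
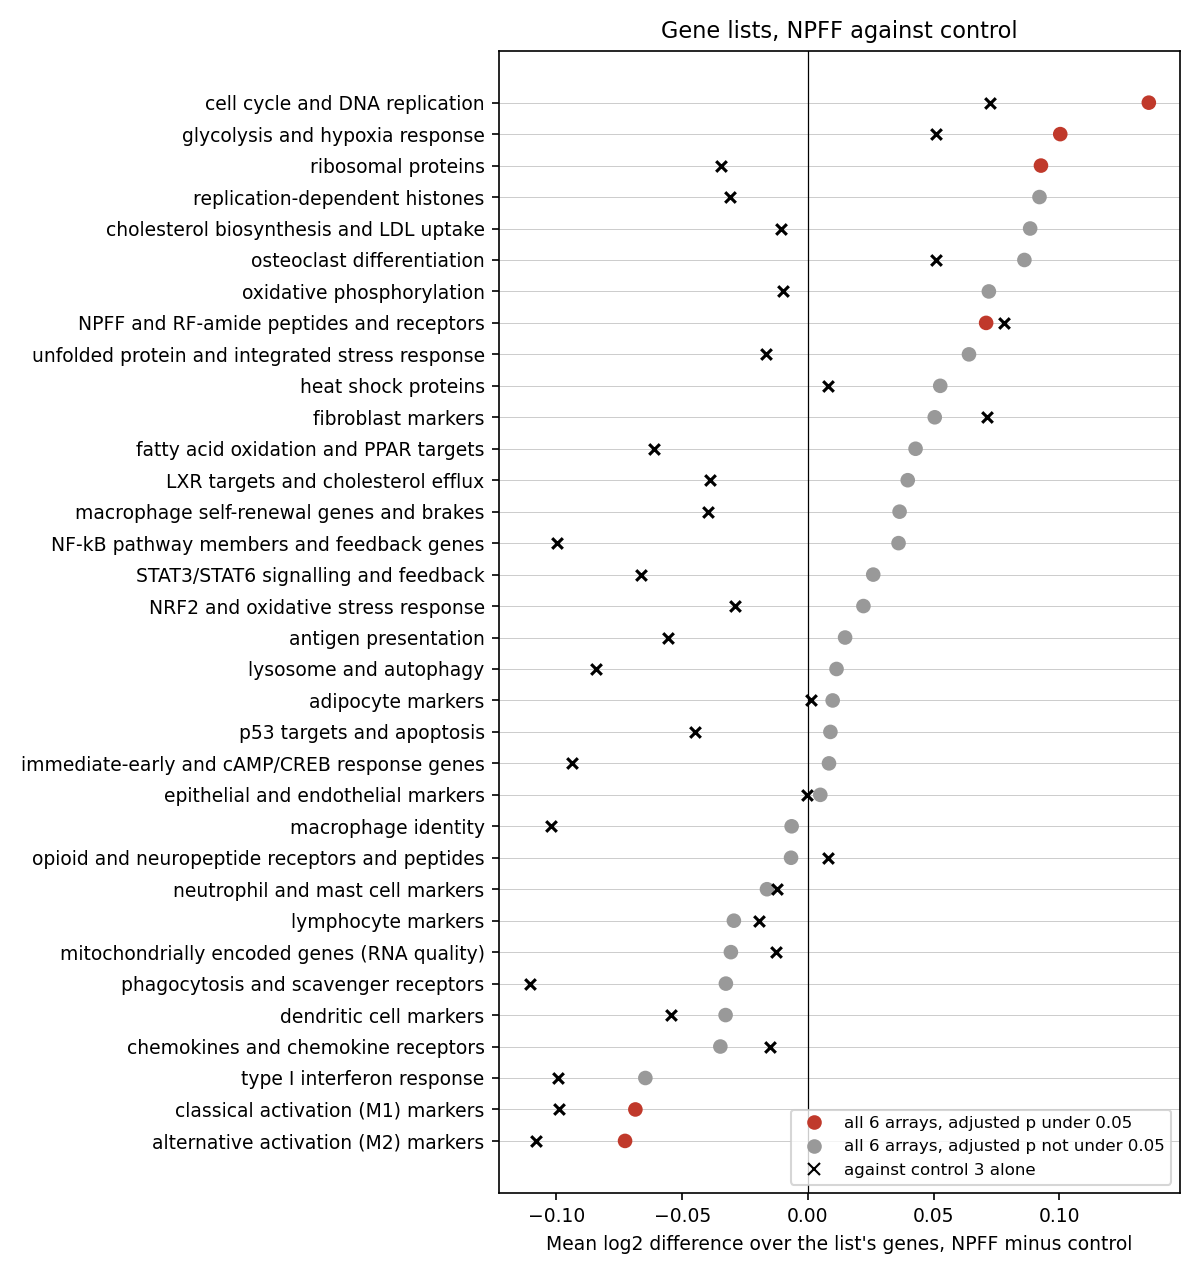
Each row is a gene list and the horizontal axis gives the mean over its genes of the log2 difference, NPFF minus control. Circles use all 6 arrays, red where the camera adjusted p was under 0.05, and crosses set the NPFF arrays against control 3 alone. The cell cycle list has the highest mean, 0.14, and the M2 list the lowest, -0.07, while the ribosomal list moves from 0.09 to -0.03 against control 3.

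Interferon-inducible genes were lower in NPFF in 21 of 34 cases, with a mean difference of -0.06, and did not pass (adjusted p = 0.0571). In 16 other settings of camera at the preset correlation the list was lower throughout and passed in 7, among them cyclic loess (0.0423). These settings reuse the same 6 arrays, of which control 3 had the highest list mean, 7.96, against 7.91 in controls 1 and 2. The adjusted p was 0.781 with an estimated correlation and 0.667 by fry. Against control 3 alone, 6 of 34 were higher. Besides Ifi204, Ifi205 had a difference of -0.78 (SE 0.25), Ifit3 -0.39 (SE 0.16) and Trim30a -0.36 (SE 0.07); without control 1, Ifi205 differed by -0.49 and Ifit3 by -0.21. Adjusted over the list alone, Ifi204 and Trim30a passed limma, and over all genes 0 did. Osteoclast differentiation genes were higher in 10 of 14 cases (adjusted p = 0.055), with Car2 and the matrix metalloproteinase Mmp9, at 0.32 (SE 0.08), passing when adjusted over the list alone. The list's median of 0.05 turned to -0.02 without control 1. Camera's direction stayed higher in 16 other settings at the preset correlation, and the list passed in 3, without control 2, NPFF 1 or NPFF 2. Its adjusted p was 0.996 with an estimated correlation. Fry's test for change in either direction gave an adjusted p = 0.0377 for this list and 0.0209 for the NPFF and RF-amide list. Phagocytosis and scavenger receptor genes were divided 16 to 16 (adjusted p = 0.079), with 7 of 32 higher against control 3 alone and a median of -0.11 without control 1, and passed as lower in 5 of 16 other settings, among them without control 1 (9.7e-04) and cyclic loess (0.0396). Fatty acid oxidation and PPAR targets were higher in 18 of 24 cases (adjusted p = 0.726); Cd36, a member of this list and the phagocytosis list, passed when adjusted over either list alone. Against control 3 alone 5 of the 24 fatty acid oxidation genes were higher, and their median of 0.04 turned to -0.05 without control 1. The Fc receptor gamma chain Fcer1g had a difference of -0.19 (SE 0.07).

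Signalling lists did not pass camera with all 6 arrays, and the medians of the NF-kB, STAT3/STAT6 and immediate-early lists changed sign without control 1. NF-kB pathway genes were higher in 20 of 29 cases (adjusted p = 0.941), but in 5 of 29 against control 3 alone, with a median of 0.05 that turned to -0.05 without control 1. The list passed as lower without controls 1 and 2 (adjusted p = 2.1e-04) and with array weights (8.7e-04). The subunit Rel had a difference of -0.36 (SE 0.10) and Birc3 -0.29 (SE 0.07). Immediate-early and cAMP response genes had an adjusted p = 0.988, with Rgs2, a regulator of G-protein signalling, at -0.46 (SE 0.11) and Btg2 at 0.23 (SE 0.08). STAT3/STAT6 signalling genes had an adjusted p = 0.982, with Il10rb at -0.20 (SE 0.06) and Pim3 at -0.18 (SE 0.06), and passed as lower without controls 1 and 2 (0.0145) and with array weights (0.0188). The immediate-early list passed as lower without control 1 (0.0178) and without controls 1 and 2 (0.0212). Opioid and other neuropeptide genes had an adjusted p = 0.956, and chemokines and their receptors 0.587, with Ccr2 at -0.35 (SE 0.13), or -0.21 without control 1. Macrophage identity genes had an adjusted p = 0.587, with Aif1 at -0.36 (SE 0.08) and C1qa at -0.28 (SE 0.10).

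Metabolic and stress lists other than glycolysis did not pass with all 6 arrays either. The camera adjusted p was 0.0851 for the unfolded protein response, with Pdia6 at 0.23 (SE 0.09) and Sdf2l1 at 0.34 (SE 0.14), or 0.15 and 0.18 without control 1, 0.239 for oxidative phosphorylation, 0.654 for cholesterol biosynthesis, 0.956 for LXR targets, 0.988 for the NRF2 response, 0.587 for heat shock proteins and 0.654 for p53 targets and apoptosis. It was 0.982 for lysosome and autophagy, 0.982 for antigen presentation, where Erap1 had a difference of -0.24 (SE 0.07), and 0.772 for mitochondrially encoded genes. Without control 1 the p53 list and the lysosome and autophagy list passed camera as lower, as both did with gene-by-gene array weights. Against control 3 alone, 5 of 35 lysosome and autophagy genes were higher. Mean or median and test differed in sign with all 6 arrays for the p53, lysosome, antigen presentation, STAT3/STAT6, immediate-early, and epithelial and endothelial lists. Their camera adjusted p all lay above 0.6 in that fit. Markers of other cell types gave adjusted p of 0.587 for fibroblasts, 0.982 for epithelial and endothelial cells, 0.523 for lymphocytes, 0.654 for neutrophils and mast cells, 0.654 for dendritic cells and 0.982 for adipocytes. Of the 34 lists, 6 passed camera at the preset correlation, 4 higher and 2 lower, whereas 0 passed with an estimated correlation and 0 passed fry. The test with an estimated correlation rests on 4 residual degrees of freedom and had little power, so its count of 0 does not decide whether correlated members produced the calls. Without controls 1 and 2 together, 14 lists passed at the preset correlation, 4 higher (cell cycle, glycolysis, NPFF and RF-amide, and fibroblast markers) and 10 lower (M1, M2, interferon, NF-kB, STAT3/STAT6, immediate-early, fatty acid oxidation, lysosome, phagocytosis and macrophage identity), in a fit where control 3 was the lone control and was assumed to vary as the NPFF arrays did. Without control 1 alone, the median changed sign in 16 of the 34 lists, of which 15 had a median above 0 with all arrays.

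**Figure D3:**
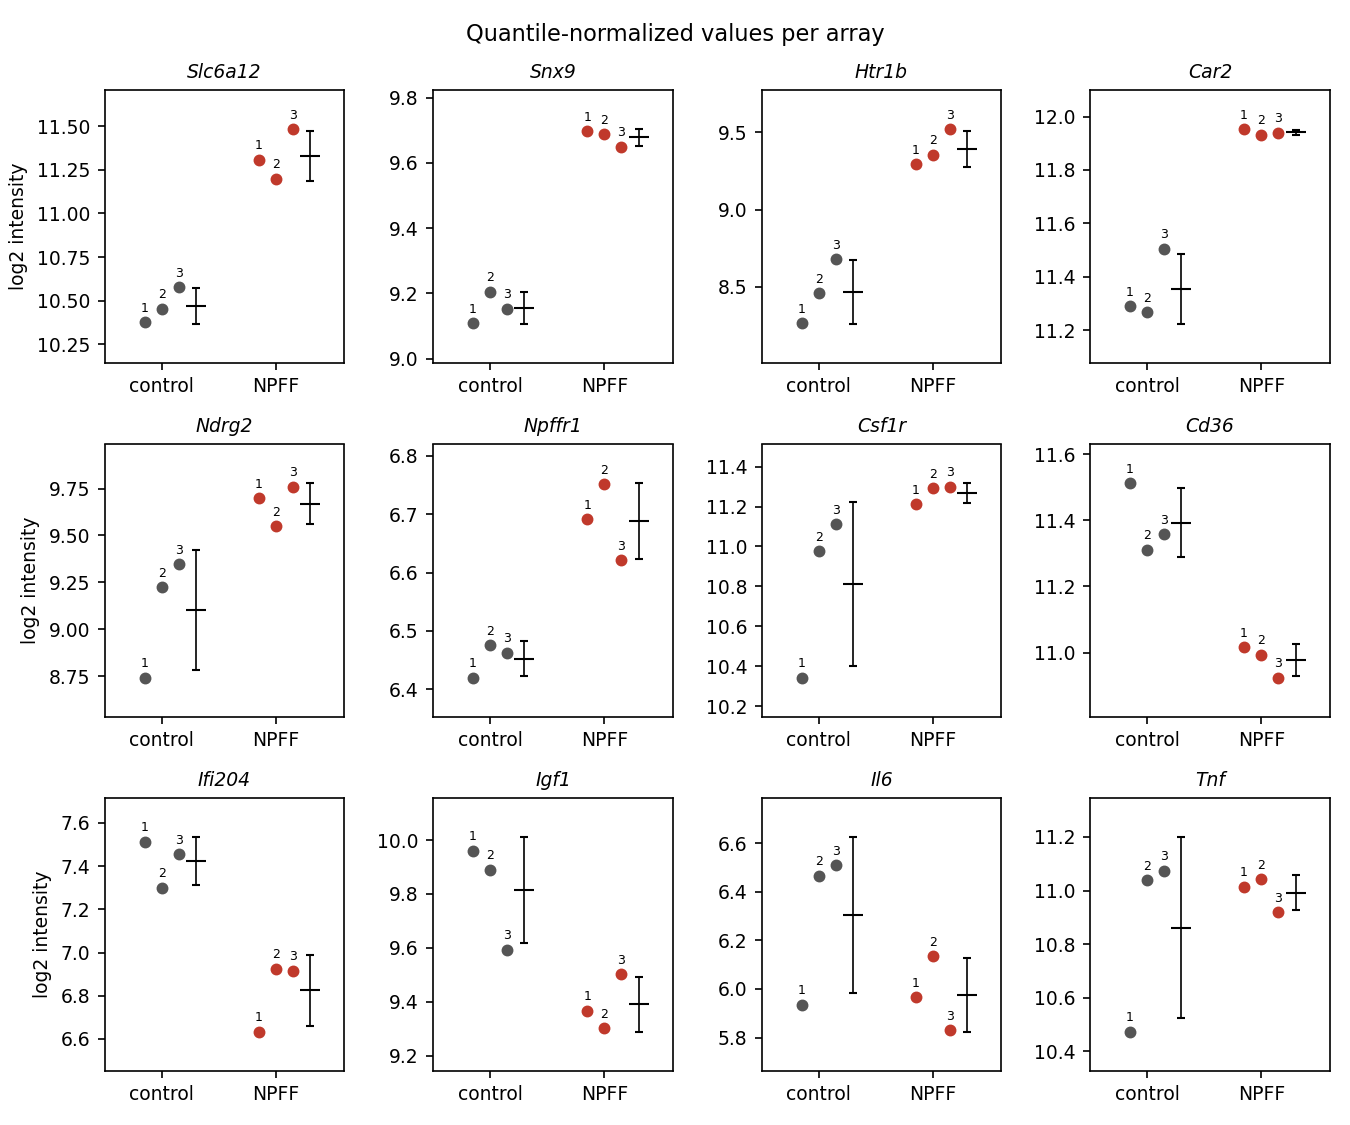
Each panel plots a gene's quantile-normalized log2 intensity in the 3 control arrays (grey) and the 3 NPFF arrays (red), numbered by replicate, with the group mean and SD as a black bar beside them. Vertical axes differ between panels and do not start at 0. The Slc6a12, Snx9, Htr1b and Car2 values of all NPFF arrays lie above all controls, while the low values of Ndrg2, Csf1r and Tnf in control 1 widen the control spread.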

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

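The values as deposited, the removal of controls 1 and 2 together and the gene-by-gene array weights were chosen after the data were seen, and all other settings before. The count of genes past the threshold was 0 by limma under every setting except array weights, which called 1127 genes, 418 higher and 709 lower, from weights whose estimation did not reach its tolerance. With weights from the gene-by-gene method 0 were called; 7 were called with array weights after cyclic loess where the tolerance was reached, and 0 with array weights on the values as deposited, where it was not. The weight of control 3 was 22.6 after quantile normalization, 3.92 after cyclic loess and 0.297 on the values as deposited, so the 1127 calls compare NPFF with control 3 above all. Of the 88 genes followed, 48 passed with array weights and kept their direction. The number of lists past the threshold was 6 with the values as deposited, with median centring and with a trended and robust prior, 8 with cyclic loess, 4 without the dimmest genes, 5 with the replicate block, 3 with the mean over a gene's features, 12 with array weights, 13 with gene-by-gene array weights and 14 without controls 1 and 2. It was 0 with an estimated correlation and 0 with fry, and between 2, without control 3, and 7 when single arrays were left out. The cell cycle list kept its call and direction in all of these except the estimated correlation (adjusted p = 0.438) and fry (0.521). With single arrays left out, its adjusted p lay between 3.3e-09 and 2.4e-04.

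With an estimated correlation, the adjusted p was 0.438 for the M2, M1 and NPFF and RF-amide lists and 0.996 for the glycolysis and ribosomal lists. The estimate was -0.050 for the NPFF and RF-amide list and 0.0056 for the M1 list, below the preset 0.01. A higher correlation among members therefore did not cost these lists their calls. With an estimated correlation camera rests on 4 residual degrees of freedom, which raises p by itself. The unadjusted camera p went from 0.00686 to 0.0460 for the M1 list and from 0.00851 to 0.0515 for the NPFF and RF-amide list. The estimate was 0.014 for the M2 list, 0.098 for cell cycle, 0.290 for ribosomal proteins and 0.342 for glycolysis. How much these estimates added to the loss of the calls was not tested. By fry the adjusted p was 0.667 for the M2 and M1 lists, 0.331 for the NPFF and RF-amide list and 0.992 for the glycolysis and ribosomal lists. Without the dimmest genes the adjusted p was 0.114 for the NPFF and RF-amide list, 0.0580 for glycolysis and 0.0743 for ribosomal proteins, and with the mean over a gene's features it was 0.0514 for both the M1 and the NPFF and RF-amide list and 0.0831 for ribosomal proteins. The ribosomal list turned to lower in NPFF with array weights (adjusted p = 0.633) and without controls 1 and 2 (0.382), and lost its call with gene-by-gene array weights (0.811). With single arrays left out, adjusted p ranged from 0.00241 to 0.0659 for the M2 list, 0.00845 to 0.333 for M1, 0.00790 to 0.486 for NPFF and RF-amide, 0.00557 to 0.130 for glycolysis and 0.00134 to 0.489 for ribosomal proteins. Of the 28 lists not called, 20 changed direction in at least 1 setting and 12 passed in at least 1, 10 as lower and 2 as higher. The cause of these changes among the 28 lists was not tested.

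Some genes changed sign. With array weights the log2 difference was 0.0740 for Npff, -0.119 for Npffr2, -0.162 for Il4ra, -0.0760 for Tnf and -0.00706 for Rpl14, and without controls 1 and 2 it was 0.0741, -0.139, -0.174, -0.0820 and -0.0131 for the same genes. With gene-by-gene array weights it was 0.0203 for Npff, -0.0319 for Npffr2, -0.111 for Il4ra and -0.0480 for Tnf. With single arrays left out it ranged from -0.100 to 0.0914 for Npffr2, -0.420 to 0.437 for Chil3, -0.115 to 0.272 for Il4ra, -0.0932 to 0.0480 for Nos2, -0.0639 to 0.237 for Tnf, -0.111 to 0.0453 for Il1b and -0.0430 to 0.00765 for Il12b. None of the 88 genes followed changed sign under another scaling. The cause was not tested.

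The titles do not say that replicate numbers mark a shared culture day, so the numbers were not taken to pair the samples. Deviations of same-numbered samples from their group means had correlations across genes of 0.230, 0.451 and -0.331. These cannot decide pairing, since control 1 dominates the deviations of its group. Controls 2 and 3 both correlated with NPFF 2, at 0.451 and 0.413. With the replicate block, 0 genes passed, 396 had an unadjusted p under 0.05, and 5 lists passed, the NPFF and RF-amide list being lost (adjusted p = 0.122). Signal over background could not be assessed, since the deposited values carry no detection measure used here. In a simulation with the spread of the real arrays, 34.3% of changes of 0.5 log2 and 93.9% of changes of 2 log2 were recovered for this comparison, so most changes of 0.5 log2 would be missed.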

Other observations

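Of the tests in this part, the comparison with brightness-matched random lists was set before its result was seen; the splits of the samples, the comparison with control 3, the tests of controls 1 and 2 and the symbol families were chosen afterwards.

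Some interferon-inducible genes besides Ifi204 and Ifi205 had lower signals in NPFF. Ifi202b stood at 8.82 ± 0.23 (SD, n = 3) in control and 8.36 ± 0.08 (SD, n = 3) in NPFF, and Ifi207 and Ifi209 had differences of -0.41 (SE 0.17) and -0.28 (SE 0.08), or -0.24 for each without control 1. Among Toll-like receptors, Tlr8 had a difference of -0.39 (SE 0.09) and Tlr9 of -0.26 (SE 0.10). Genes whose symbols begin with Nop, several of which encode nucleolar proteins of ribosome assembly, were higher in 8 of 8 cases, with Nop58 at 0.17 (SE 0.07) and Nop56 at 0.19 (SE 0.10), or 0.17 and 0.08 without control 1. None of these genes passed limma over all genes. They were chosen after their values were seen.

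Among 319 families of symbols with a shared stem, camera at the preset correlation called 4, of which Ifi genes were lower in 10 of 14 cases (median -0.23, adjusted p = 0.00487), Tlr genes lower in 10 of 12 (median -0.12, adjusted p = 0.0290), Nop genes higher in 8 of 8 (median 0.16, adjusted p = 0.00219) and Dhx genes higher in 14 of 16 (median 0.16, adjusted p = 0.0290). With an estimated correlation none did, at an adjusted p of 0.995 for each. Unadjusted, that camera p lay between 0.0176 for Ifi and 0.217 for Dhx among these 4. On 4 residual degrees of freedom and over 319 families this test could hardly call any family, so it decides nothing here. The direction of each median was the same with the values as deposited, with median centring and with cyclic loess. Against control 3 alone the medians were -0.14, -0.08, 0.07 and 0.01. A coordinated shift of these families may underlie this, but members that vary together across these 6 arrays for any reason cannot be told apart from members that respond to NPFF.

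The cell cycle and DNA replication list was higher in NPFF. Brightness alone seldom gave such a shift. The list's median difference lay at the 99.98th percentile of 10000 random lists matched on mean expression. Genes of these random lists were drawn independently, so a list whose genes vary together can reach a high percentile without responding to NPFF. Glycolysis and ribosomal lists lay at the 99.07th and 98.99th percentiles, yet their medians fell to 0.01 and 2.7e-04 without control 1. Against control 3 alone these 2 lists parted. The glycolysis median was 0.05, with 24 of 30 genes higher, and the ribosomal median -0.03, with 14 of 42 higher. Control 1 may contribute, as the mean fell from 0.14 to 0.07 without it and was also 0.07 without controls 1 and 2. From the mean of all arrays, the list lay at -0.19 in control 1, but at -0.008 and -0.005 in controls 2 and 3. In the simulation where control 1 carried its real deviation and NPFF had no effect, the mean difference was 0.0975. The list did not pass camera there (adjusted p = 0.116). That simulation gave control 2 no deviation, drew noise independently between genes and was run once. It therefore cannot exclude that the deviating controls yield such a call. Against control 3 alone the median difference of 0.08 lay at the 100th percentile, above all 10000 random lists, with 47 of 55 genes higher. A single control array leaves open how much the other controls contribute. Of the 10 splits of the 6 arrays, 1, the real split, gave a p as small (1.5e-10, against 7.1e-04 in the next), and 10 splits are too few for a share under 0.05. A response to NPFF stays among the open explanations.

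Counts from other splits of the arrays bear on the remaining results, and again 10 splits are too few for a share under 0.05. As many genes passed in 10 of the 10 splits, the real count and the highest other both being 0. At least 6 lists passed in 4 of the 10 splits, with 6 in the real split and up to 8 in the others. At an unadjusted p under 0.05 the other 9 splits gave between 174 and 2179 genes, fewer than the 556 of the real split in 5 and more in 4; the highest count was that of control 1, NPFF 1 and NPFF 3 against the rest.

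Controls 1 and 2 stood apart from the other 4 arrays, and the design offers no group that would give a biological explanation, so none was tested. A signal scale that depends on brightness would be removed with a smooth trend, yet the spread left for control 1 was 2.99 times the largest of the other 4 arrays, each measured from the mean of the other 3. For control 2 the same ratio was 1.45 before and 1.449 after the trend was removed, under the line of 1.5 in both cases, so this test leaves the explanation open there. Cells of another type would raise their markers, and the highest median among 6 marker lists lay at the 66.46th percentile of matched random lists in control 1, for fibroblasts (brightest member Acta2, 8.998), and at the 96.23rd in control 2, for adipocytes (brightest member Lpl, 10.22, which macrophages also express), near the limit set for the test. Background signal stays open for control 1, where unnamed features exceeded named ones of like brightness by 0.110 log2 (SE 0.0409 over 20 bins), above the line of 0.1 by less than the SE. Unnamed features were higher in 13 of the 20 bins, and the bins ranged from -0.0468 to 0.553. The bins come from 1 array, so this SE is no spread between samples, and control 2 was not examined in this way. RNA quality was not tested; the mitochondrial transcripts deviated upward in control 1 and downward in control 2.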
